A study of Mus musculus with 3 samples.

How the data were processed

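Gene expression was measured in 3 populations of endosteal cells from C57BL/6 mice. Per the labels, fragments of femur and tibia were digested with collagenase, cells negative for CD45, CD31 and Ter119 were kept, and the remainder was sorted by PDGFRα and Sca-1 into PDGFRα−Sca-1−, PDGFRα+Sca-1− and PDGFRα+Sca-1+ cells. CD45, CD31 and Ter119 mark blood cells, endothelial cells and erythroid cells. Per the labels' protocols, total RNA was amplified and biotin-labelled with a two-cycle assay, which amplifies the RNA in a pair of rounds, and hybridised to 1 Affymetrix expression array per population.

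The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were computed with MAS5, the array maker's summary of perfect-match and mismatch probes; its version, the detection calls and any filter are not given in the sources used here. In the values themselves, the 2% trimmed mean over all 45101 probe sets was 500 on each array, so the arrays had been brought to a common level before deposition. The signals ran from 0.1 to 40706.7 in PDGFRα−Sca-1− cells, to 38540.2 in PDGFRα+Sca-1− cells and to 42073.9 in PDGFRα+Sca-1+ cells. Saturation can compress signals near the top of this range, so ratios that rest on them carry no exact size. The medians were 95.2, 96.6 and 88.3 in the same order.

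The remaining steps were computed here. After 64 control probe sets were set aside, each array was scaled to a common 2% trimmed mean over the other 45037. A common floor was set at the mean of the 3 array medians, a signal of 93.2, in place of detection calls. Signals under the floor were raised to it before log2 was taken. Gene names came from the platform annotation given with the data: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34741 were matched by gene number to the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols were changed by it. Each of the resulting 18193 genes took the value of its probe set with the highest mean log2 signal. Probe sets with several symbols or none entered no comparison of genes; probe sets shared only between globin genes were read only as a class, to look for erythroid cells. The gene encoding Sca-1 and several other list members, among them Runx2, Bglap and Spp1, had no probe set with a single symbol and are not analysed here.

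With 1 array per population there was no replicate, so no p-value, standard deviation over replicates or test of a difference between populations was computed. The number of arrays limits the precision of each value. A gene was counted as higher or lower where the ratio was 2-fold or more. A gene under the floor on 1 of the 2 arrays has only a bound, written as "at least", with no order among such bounds, and a gene under the floor on both was not compared. The only repeated measurement was that of different probe sets of the same gene. The SD of their log2 ratios was 0.60 for PDGFRα+Sca-1+ over PDGFRα+Sca-1−, 0.37 for PDGFRα+Sca-1− over PDGFRα−Sca-1− and 0.50 for PDGFRα+Sca-1+ over PDGFRα−Sca-1−. It covers scatter between probes and transcripts, not between animals or arrays.

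For each of 37 fixed gene lists, the median log2 ratio was taken over the members above the floor on at least 1 of the arrays, with members under the floor on the other array entered at the floor. For lists with at least 5 such members, the median was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is not a p-value. Genes named in the text were chosen by a fixed rule. It took the gate markers, then, per comparison and direction, the 6 largest ratios measured on both arrays and the 6 brightest genes with the other array under the floor. It then took 6 genes per population with the largest smaller ratio against both others, and, per list, up to 4 members with the largest ratios, bounds entered at the floor, and up to 2 members within 2-fold or going the other way. Symbols that only number a clone or predicted gene were passed over.

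The counting of genes was tested on simulated gene values in which 200 of the 18193 genes were changed. The 200 were drawn from genes with a mean signal at least 4 times the floor, so recovery among dimmer genes was not tested. The choice of probe set was not part of this simulation. At a simulated 4-fold change it recovered 98.0% for PDGFRα+Sca-1+ over PDGFRα+Sca-1−, 98.5% for PDGFRα+Sca-1− over PDGFRα−Sca-1− and 98.5% for PDGFRα+Sca-1+ over PDGFRα−Sca-1−. At a simulated 2-fold change, which sits on the threshold, it recovered 51.0%, 45.5% and 44.0% in the same order, and it called 3.99%, 3.74% and 3.77% of the unchanged genes. The simulated noise had the same SD of log2 signal, 0.347 per array, in all 3 comparisons, so these values repeat 1 setting. They are not rates for each comparison, because the scatter between probe sets differed between the comparisons. The alternatives were the values as deposited, median centring, quantile normalization, floors at the 33rd and 67th percentiles, a pseudocount in place of the floor, the mean over a gene's probe sets, leaving out probe sets shared between transcripts, and a 3-fold threshold. Groups, comparisons, gene lists, the naming rule and these alternatives were fixed before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.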

Results

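Mouse cells described as endosteal, from the inner surface of bone, were sorted into 3 populations profiled on 1 array each: PDGFRα−Sca-1−, PDGFRα+Sca-1− and PDGFRα+Sca-1+. Cartilage genes were bright in the Sca-1− populations, with mean signals over their arrays of 27041 for Col2a1 and 26442 for Acan. The sorted fractions are therefore not shown to hold bone-lining cells alone. PDGFRα is a receptor for platelet-derived growth factor found on mesenchymal cells, and Sca-1 is a surface protein used to enrich mesenchymal progenitors. The series compared the 3 sorted fractions with each other. Signals lay above the floor for 11026 genes in PDGFRα−Sca-1− cells, 11042 in PDGFRα+Sca-1− cells and 10846 in PDGFRα+Sca-1+ cells. Each population had 1 array, so none of the differences below has a replicate check.

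The gate markers were read before any comparison. The Pdgfra signal was 586 in PDGFRα−Sca-1− cells, 2420 in PDGFRα+Sca-1− cells and 12846 in PDGFRα+Sca-1+ cells. It was thus lowest in the population labelled PDGFRα−, though above the floor there, and 4.13-fold higher in PDGFRα+Sca-1− cells. It was also 5.31-fold higher in PDGFRα+Sca-1+ than in PDGFRα+Sca-1− cells, a difference that the labels do not set. Ptprc, which encodes CD45, stayed under the floor of 93.2 on all 3 arrays, with a highest signal of 74.1. Pecam1, which encodes CD31, was also under the floor on all 3, at 10.7, 7.51 and 4.69. The gene for Sca-1 is not analysed here, so its level does not check the labels. The PDGFRα−Sca-1− and PDGFRα+Sca-1− profiles were the closest pair, with a Pearson correlation across 12211 genes of 0.929. It was 0.796 between the PDGFRα+ arrays and 0.781 between PDGFRα−Sca-1− and PDGFRα+Sca-1+. Genes are not independent replicates, so these values only describe the arrays. The control probe sets at the 3' and 5' ends of Actb gave signal ratios of 2.99, 2.63 and 4.65 in PDGFRα−Sca-1−, PDGFRα+Sca-1− and PDGFRα+Sca-1+ cells, and those of Gapdh gave 3.93, 3.54 and 4.73. The 3' end was therefore more favoured on the PDGFRα+Sca-1+ array than on the others.

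**Figure D1:**
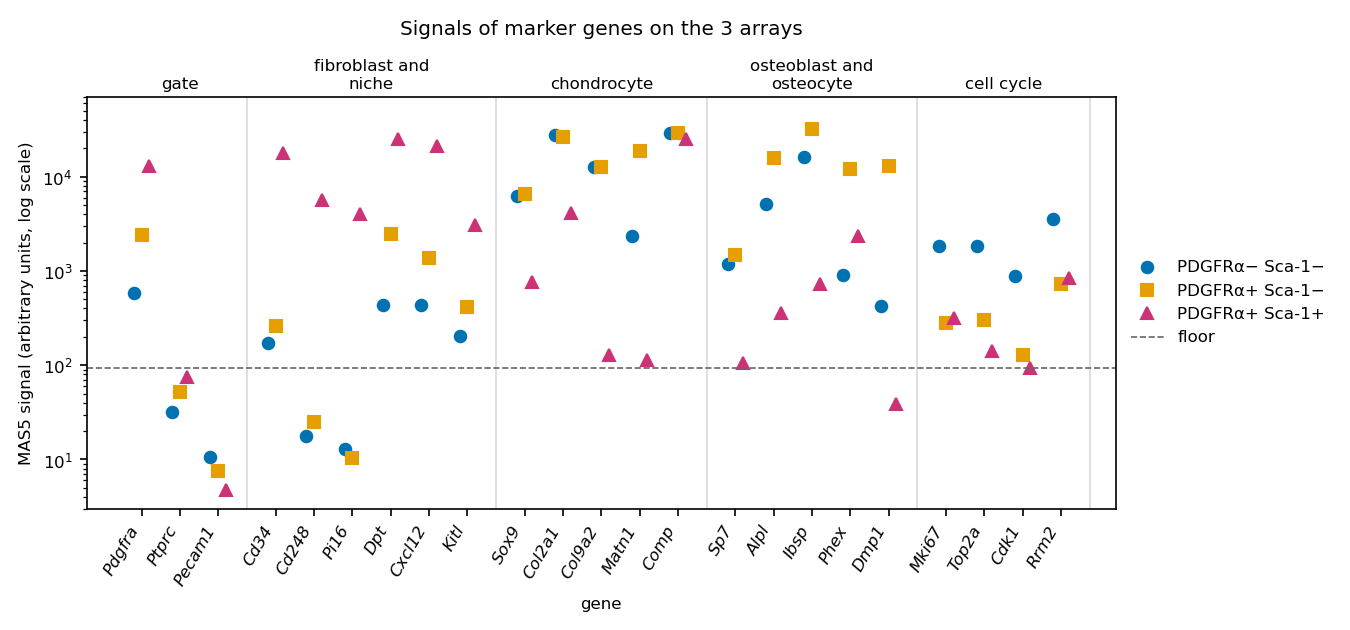
MAS5 signal (vertical axis, arbitrary units, log scale) of 23 marker genes (horizontal axis) in PDGFRα−Sca-1− (circles), PDGFRα+Sca-1− (squares) and PDGFRα+Sca-1+ cells (triangles), 1 array each; the dashed line is the floor of 93.2. Cd34 stands at 17639 in PDGFRα+Sca-1+ cells against 258 and 172 in the others, while Dmp1 stands at 12890 in PDGFRα+Sca-1− cells.

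The comparison of PDGFRα+Sca-1+ with PDGFRα+Sca-1− cells asked which transcripts go with Sca-1 among PDGFRα+ cells, although these populations also differed in their Pdgfra signal. Most genes in the lists of fibroblasts and adventitial stroma, complement, chemokines and haematopoietic niche factors were at least 2-fold higher in PDGFRα+Sca-1+ cells. Most chondrocyte and osteoblast genes were lower. The niche list holds general cytokines and growth factors beside factors of the blood-forming marrow. Cd34, a sialomucin of stromal and blood progenitors, was 68.3-fold higher, at 17639 against 258. Matn1, a cartilage matrix protein, was 163-fold lower, at 115 against 18704. Of 11855 genes compared, 1763 were at least 2-fold higher in PDGFRα+Sca-1+ cells and 1340 at least 2-fold lower, 26.2% in all. The ratio was 10-fold or more for 150 genes in the upward direction and for 141 in the downward direction.

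Next to Cd34, the largest ratios measured on both arrays belonged to Mfap5, a microfibril protein (60.4-fold), the transcription factor Ebf2 (45.4-fold), the amine oxidase Aoc3 (42.8-fold), Ms4a4d (40.0-fold) and the chemokine-binding receptor Ackr1 (39.6-fold). The brightest genes that lay under the floor in PDGFRα+Sca-1− cells were Cd248 (endosialin, at least 60.3-fold), Mndal (at least 50.9-fold), Efhd1 (at least 45.5-fold), Pi16 (at least 42.7-fold), Scg3 (at least 42.2-fold) and Calcrl (at least 24.9-fold). In the other direction, Matn1 was followed by the carbonic anhydrase gene Car3 (137-fold lower), the cartilage collagens Col9a2 (97.4-fold) and Col10a1 (89.4-fold), the channel gene Panx3 (84.7-fold) and the coagulation factor gene F5 (80.9-fold). The other Panx3 probe set had a log2 ratio of only −1.62. Dmp1, a matrix protein of osteocytes, was at least 138-fold lower in PDGFRα+Sca-1+ cells. It was joined under the floor there by Krtap17-1 (at least 117-fold), the Wnt antagonist Frzb (at least 75.1-fold), Il17b (at least 74.8-fold), Slc38a4 (at least 61.2-fold) and Ncmap (at least 53.4-fold).

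**Figure D2:**
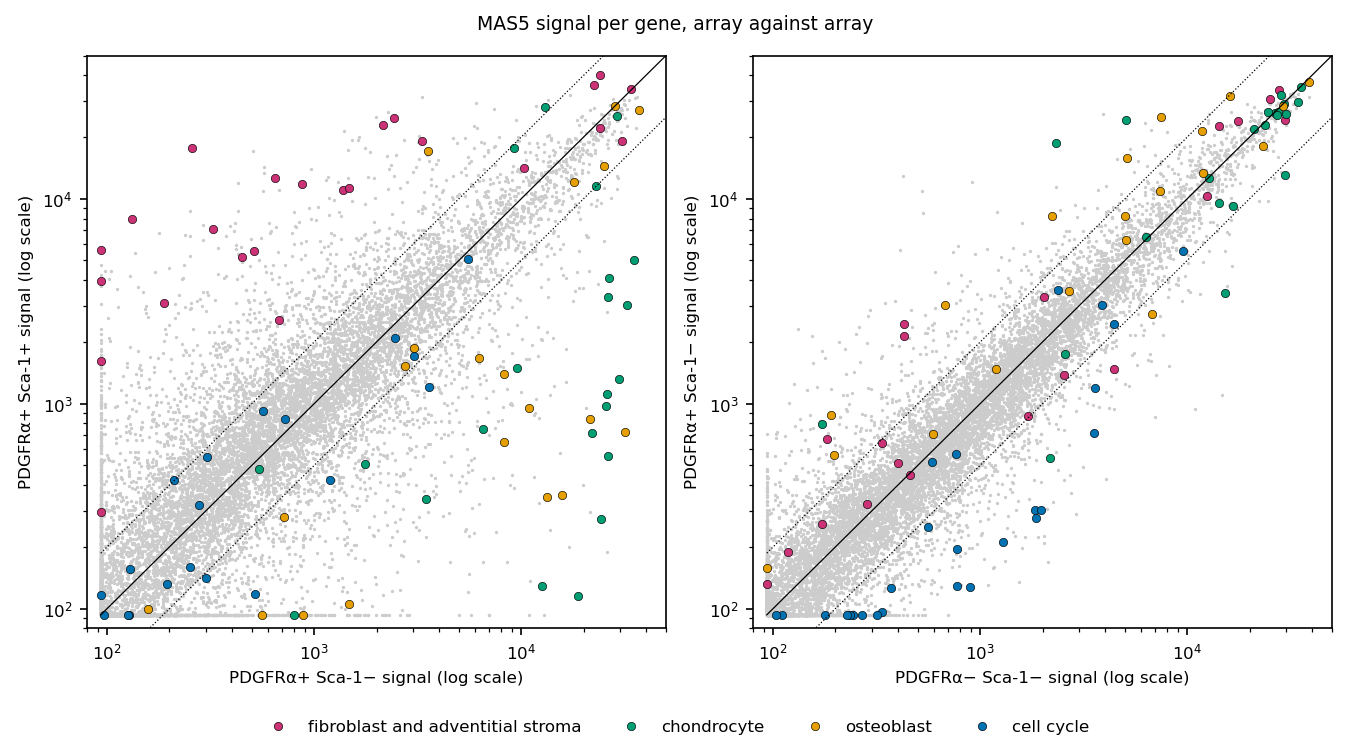
Signal per gene on a log scale, PDGFRα+Sca-1+ against PDGFRα+Sca-1− cells (left) and PDGFRα+Sca-1− against PDGFRα−Sca-1− cells (right), with signals under the floor drawn at 93.2; grey points are genes above the floor on at least 1 of the arrays, coloured points are members of the fibroblast (pink), chondrocyte (green), osteoblast (orange) and cell cycle (blue) lists, the solid line marks equal signal and the dotted lines a 2-fold ratio. Outside 2-fold lay 26.2% of the genes compared in the left panel and 10.4% in the right panel.

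Of 24 fibroblast and adventitial stroma genes compared, 18 were at least 2-fold higher in PDGFRα+Sca-1+ cells, 0 lower and 6 within 2-fold, with a median log2 ratio of 3.38. Cd34, Mfap5, Cd248 and Pi16 were among those higher, and the abundant proteoglycan gene Lum (log2 ratio −0.11) was among those within 2-fold. Dcn had a log2 ratio of 0.01 by its brightest probe set, whose signals lay near the top of the arrays' range, but 1.94 by its other probe set. Haematopoietic niche factors were higher for 13 of 17 genes and lower for 4, with a median of 2.55 that fell to 1.13 with the mean over probe sets. Ccl2 was 25.9-fold, Il6 20.5-fold and Fgf7 19.1-fold higher, whereas the N-cadherin gene Cdh2 was at least 19.5-fold lower and Lif 3.31-fold lower. Of 19 genes of CXCL12-abundant reticular stroma, a marrow support cell, 13 were higher, 1 lower and 5 within 2-fold, with a median of 2.03. Among them Ebf1 was 18.9-fold, the chemokine gene Cxcl12 15.4-fold, Gas6 9.54-fold and Serping1 9.47-fold higher, the last at a signal of 31357 near the top of the range, although the lowest of the 3 Cxcl12 probe sets had a log2 ratio of 0.08, while Adipoq was at least 3.16-fold lower and Foxc1 had a log2 ratio of −0.64. Of 13 mesenchymal progenitor surface markers, 6 were higher, 3 lower and 4 within 2-fold, with a median of 0.40. Thy1 was 25.6-fold and Vcam1 8.22-fold higher, and Nt5e was 20.1-fold and Cd200 8.86-fold lower. Mesenchymal transcription factors were higher for 12 of 21 genes, lower for 3 and within 2-fold for 6. Meox2 (17.5-fold), Osr2 (8.78-fold), Prrx1 (8.55-fold) and Twist2 (7.05-fold) were among those higher, and Foxc2 was 5.88-fold lower.

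Complement genes were higher for 7 of 9 members, lower for 0 and within 2-fold for 2, with a median log2 ratio of 3.24. Cfb was 26.3-fold, Cd55 16.4-fold, C1ra 11.6-fold and C1s1 10.9-fold higher. Chemokines and cytokines were higher for 14 of 22 genes, lower for 2 and within 2-fold for 6, with a median of 1.89. Cxcl2 (27.9-fold), Ccl2, Il6 and Cxcl12 were among those higher, and Il11 was 10.6-fold lower. Interferon-response genes were higher for 11 of 16 members and lower for 0, with a median of 1.41; the RNA sensor Ifih1 was 10.8-fold, Usp18 at least 6.65-fold, Oasl2 at least 5.45-fold and Psmb8 at least 4.78-fold higher. Each of these 3 lists, and the fibroblast, niche factor, reticular stroma and transcription factor lists, had a median above that of every random list, a percentile of 100. Several of these lists share members, such as Cxcl12, Serping1 and Cd55, so they are not separate results. The matrix protease list and the mixed TGF-β and BMP pathway list, described below, also had a percentile of 100.

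Chondrocyte genes were lower for 18 of 22 members in PDGFRα+Sca-1+ cells, higher for 1 and within 2-fold for 3, with a median log2 ratio of −3.10. Besides Matn1, Col9a2 and Col10a1 they included Snorc, 47.6-fold lower. The lubricin gene Prg4, a product of superficial joint cartilage and synovium, was 2.15-fold higher, and Comp, at signals near the top of the range, had a log2 ratio of −0.20. Osteoblast genes were lower for 12 of 20 members, higher for 1 and within 2-fold for 7, with a median of −2.24. Alkaline phosphatase (Alpl) was 44.3-fold, bone sialoprotein (Ibsp) 43.5-fold, Col11a2 38.2-fold and the parathyroid hormone receptor Pth1r 25.5-fold lower, while Postn was 4.81-fold higher. The Ibsp signal of 31665 in PDGFRα+Sca-1− cells lay near the top of the range, and its probe sets gave log2 ratios of −5.44 and −6.73. Of 7 osteocyte genes, 4 were lower, 1 higher and 2 within 2-fold. The chondrocyte and osteoblast medians lay below those of all random lists.

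Wnt pathway genes went both ways, with 9 of 23 higher, 7 lower and 7 within 2-fold. The antagonists Dkk2 (28.1-fold) and Sfrp1 (16.8-fold) were higher in PDGFRα+Sca-1+ cells, whereas Frzb and Wnt4 (at least 23.8-fold) were lower. The TGF-β and BMP pathway list divided similarly, with 12 of 28 members higher, 8 lower and 8 within 2-fold. Fstl1 (12.7-fold) and Bmp4 (5.88-fold) were higher and Bmp6 (13.2-fold) and Chrdl1 (6.35-fold) lower. Matrix proteases and their inhibitors were higher for 8 of 14 genes, among them Adamts15 (at least 5.74-fold) and Adamts4 (4.51-fold), and lower for 3, among them Mmp13 (12.7-fold) and Timp1 (3.32-fold). Fibrillar and basement membrane collagens were higher for 6 of 16 and lower for 0, and the basement membrane genes Col4a1 (14.4-fold) and Col4a2 (11.2-fold) led them. Their median log2 ratio was −0.05 and their mean 0.71, of opposite sign. Of the 1539 differing genes with more than 1 probe set measured, 82.1% had every probe set on the same side. The Actb 3' to 5' signal ratio, 4.65 against 2.63, differed between these arrays, and the 2-fold threshold was 1.68 SDs of the scatter between probe sets.

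**Figure D3:**
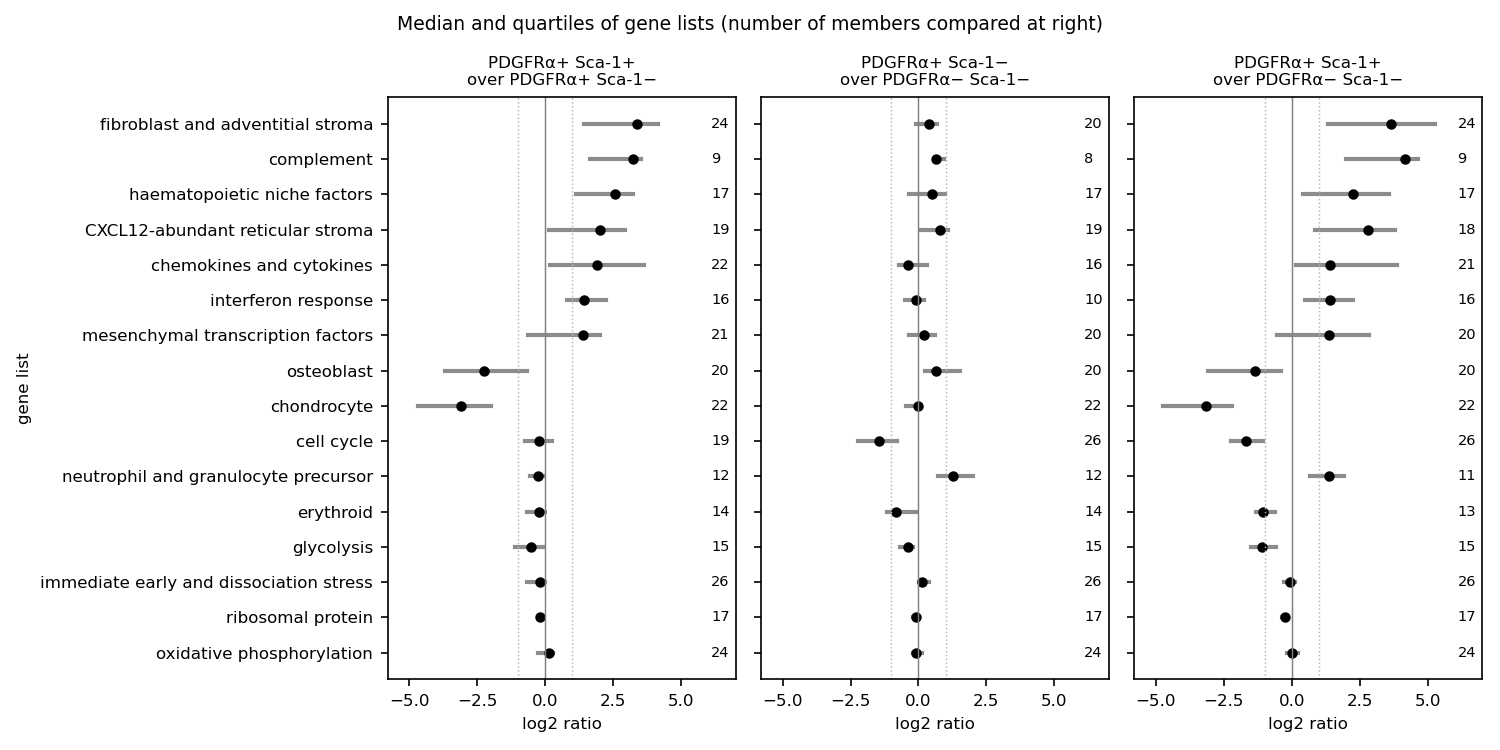
Median log2 ratio (points) and quartiles (bars) of 16 gene lists in the 3 comparisons, 1 array per population, with the number of members compared at the right and dotted lines at 2-fold. The fibroblast and complement lists lie to the right and the chondrocyte and osteoblast lists to the left in both comparisons of PDGFRα+Sca-1+ cells, and the cell cycle list lies at −1.46 in the middle panel.

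The comparison of PDGFRα+Sca-1− with PDGFRα−Sca-1− cells asked what goes with PDGFRα among Sca-1− cells. Most cell cycle genes were at least 2-fold lower in the PDGFRα+ cells and 7 of 12 neutrophil precursor genes higher. Of the osteoblast and osteocyte genes 6 of 20 and 3 of 7 were higher, and most of the others, like most cartilage genes, were within 2-fold. Dmp1 was 30.3-fold higher in PDGFRα+Sca-1− cells, at 12890 against 426, and Mki67, a marker of dividing cells, was 6.68-fold lower, at 278 against 1859. Of 11675 genes compared, 563 were at least 2-fold higher in PDGFRα+Sca-1− cells and 657 at least 2-fold lower, 10.4% in all.

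The largest ratios in favour of PDGFRα+Sca-1− cells after Dmp1 were those of Krtap17-1 (20.7-fold), Plaat3 (17.4-fold), the retinaldehyde dehydrogenase Aldh1a3 (16.1-fold), the secreted phospholipase Pla2g10 (13.9-fold) and the prostaglandin dehydrogenase Hpgd (13.6-fold). Under the floor in PDGFRα−Sca-1− cells were Mpo (at least 7.64-fold), Scara5 (at least 6.17-fold), Enox1 (at least 5.95-fold), Cavin4 (at least 5.17-fold), Eya4 (at least 5.05-fold) and Chn1 (at least 5.01-fold). The other probe sets of Scara5, Enox1 and Eya4 had log2 ratios of only 0.01, 0.88 and 0.78. In favour of PDGFRα−Sca-1− cells, the apolipoprotein gene Apoe had the largest ratio measured on both arrays, 13.4-fold, at 14749 against 1099. It was followed by the Wnt antagonist Sfrp5 (12.6-fold), C1qtnf3 (11.6-fold), the fibrinogen gene Fgg (11.5-fold), the hedgehog-binding Hhip (10.02-fold) and Scube2 (9.78-fold). The brightest genes under the floor in PDGFRα+Sca-1− cells were Oca2 (at least 7.50-fold), the kinetochore genes Nuf2 (at least 5.83-fold) and Cenpp (at least 5.65-fold), Atp1b2 (at least 5.10-fold), Gpr37l1 (at least 4.78-fold) and the MHC class II gene H2-Aa (at least 4.75-fold). The Cenpp probe sets ran from a log2 ratio of −2.50 to −0.18.

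Cell cycle genes were at least 2-fold lower in PDGFRα+Sca-1− than in PDGFRα−Sca-1− cells for 17 of 26 members, higher for 0 and within 2-fold for 9. Their median log2 ratio of −1.46 lay below that of all random lists. Cdk1 was 7.02-fold, Mki67 6.68-fold, Mcm5 6.47-fold and Mcm3 6.11-fold lower, and Mcm6 had a log2 ratio of 0.58. Erythroid genes moved with them: 5 of 14 were lower, 0 higher and 9 within 2-fold, with a median of −0.84. The transferrin receptor Tfrc was 3.75-fold and Hemgn 2.60-fold lower. Neutrophil and granulocyte precursor genes were higher in PDGFRα+Sca-1− cells for 7 of 12 members and lower for 0, with a median of 1.25, or 1.96 with the floor at the 33rd percentile. Besides Mpo they included S100a8 (4.62-fold), Ngp (4.34-fold) and Prtn3 (at least 3.85-fold), and their signals in PDGFRα+Sca-1− cells reached at most 712 while Ptprc stayed under the floor.

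Osteoblast genes were higher in PDGFRα+Sca-1− cells for 6 of 20 members, lower for 1 and within 2-fold for 13, with a median of 0.64 at the 100th percentile. Kcnk1 was 4.60-fold, Cdh11 4.47-fold, Mmp13 3.70-fold and Col1a1 3.36-fold higher, and Omd was 2.48-fold lower. Osteocyte genes were higher for 3 of 7 members, among them Dmp1 and the endopeptidase gene Phex (13.2-fold), and lower for 0. Chondrocyte genes were within 2-fold for 16 of 22 members, higher for 3 and lower for 3. Matn1 (8.03-fold), Col10a1 (4.80-fold) and Ihh (4.64-fold), the last 2 known from hypertrophic and prehypertrophic cartilage, were higher, and Ucma, known from early growth plate cartilage, was 4.35-fold lower. Col2a1, at 26563 against 27518, was among the members within 2-fold, with signals near the top of the arrays' range. Haematopoietic niche factors were higher for 4 of 17 genes, lower for 1 and within 2-fold for 12. Cdh2 was 10.6-fold and Cxcl12 3.18-fold higher and Il6 9.49-fold lower. The fibroblast list had 16 of 20 members within 2-fold, but Dpt (5.66-fold) and Col14a1 (5.03-fold) were higher and Efemp1 was 3.02-fold lower. Genes of reticular stroma were higher for 7 of 19 members, among them Adipoq (at least 3.16-fold) and Serping1 (2.49-fold), and lower for 1. With a floor at the 67th percentile the counts were 365 higher and 388 lower, and the 2-fold threshold was 2.69 SDs of the scatter between probe sets.

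The comparison of PDGFRα+Sca-1+ with PDGFRα−Sca-1− cells set apart the populations that differed in both sorting markers. Most fibroblast, complement and reticular stroma genes were at least 2-fold higher in PDGFRα+Sca-1+ cells, and most chondrocyte, osteoblast and cell cycle genes lower. Cd34 was 103-fold higher in PDGFRα+Sca-1+ cells, at 17639 against 172, and Col9a2 98.8-fold lower, at 129 against 12746. Of 11843 genes compared, 1713 were at least 2-fold higher in PDGFRα+Sca-1+ cells and 1443 at least 2-fold lower, 26.6% in all.

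After Cd34 came the transporter gene Abca8a (76.1-fold), the RNA-binding Celf2 (73.8-fold), the chemerin gene Rarres2 (71.1-fold), the glutathione transferase Mgst1 (60.5-fold) and the matrix protein Dpt (57.7-fold). The 5 Celf2 probe sets ran from a log2 ratio of 1.34 to 6.20. Under the floor in PDGFRα−Sca-1− cells lay the ferritin receptor gene Scara5 (at least 143-fold), Mfap5 (at least 85.6-fold), Cd248 (at least 60.3-fold), Ms4a4d (at least 58.6-fold), Mndal (at least 50.9-fold) and Aoc3 (at least 47.8-fold). Lower in PDGFRα+Sca-1+ cells, next to Col9a2, were Calml3 (69.6-fold), the cartilage gene Mia (62.4-fold), Panx3 (58.8-fold), the cGMP-dependent kinase Prkg2 (49.3-fold) and Fxyd2 (47.2-fold). The other Panx3 probe set had a log2 ratio of −0.98, within 2-fold. Ncmap (at least 79.6-fold), Mpzl2 (at least 47.3-fold), Il17b (at least 46.3-fold), Krt16 (at least 32.9-fold), Slc38a3 (at least 29.3-fold) and Frzb (at least 28.0-fold) were under the floor in PDGFRα+Sca-1+ cells.

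Fibroblast genes were higher for 19 of 24 members and lower for 0 (median log2 ratio 3.64). Complement genes were higher for 7 of 9 (4.17), reticular stroma genes for 13 of 18 (2.79) and haematopoietic niche factors for 11 of 17 (2.26). With the mean over probe sets the last 2 medians were 1.78 and 1.22. Cxcl12 was 48.9-fold, Fgf7 at least 31.2-fold, Ccl2 at least 28.1-fold and the stem cell factor gene Kitl 15.1-fold higher, while Lif was 6.52-fold lower. Chondrocyte genes were lower for 18 of 22 members (−3.14), among them Ucma (44.4-fold) and Snorc (44.3-fold), with Cilp (0.10) and Prg4 (−0.08) within 2-fold. Osteoblast genes were lower for 13 of 20 (−1.34) and higher for 2, with Col11a2 34.3-fold and Ibsp 22.1-fold lower. Cell cycle genes were lower for 20 of 26 and higher for 0 (−1.69), Top2a by 13.0-fold. The erythroid list moved with them, with 7 of 13 members lower and 0 higher (−1.04). Neutrophil precursor genes were higher for 7 of 11 and lower for 0 (1.37), with Mpo at least 7.03-fold and Lcn2 at least 5.73-fold higher. Of 7 osteocyte genes, Phex was 2.58-fold higher by its brightest probe set, but its mean over probe sets gave a log2 ratio of −0.90; Dmp1 was at least 4.57-fold lower. Here too the Actb 3' to 5' ratio was larger in PDGFRα+Sca-1+ cells, 4.65 against 2.99.

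Genes that set each population apart from both others were counted by the same 2-fold rule. PDGFRα+Sca-1+ cells stood apart with 1294 genes higher and 850 lower than in both others, PDGFRα−Sca-1− cells with 390 and 192, and PDGFRα+Sca-1− cells with 301 and 159. Both comparisons behind each count share an array, so neither is an independent check of the other. In 100 simulations of arrays that differed only by the scatter between probe sets, at most 56 genes reached any of these counts. Independent lists would have shared 263 and 157 genes for PDGFRα+Sca-1+, 83.8 and 71.7 for PDGFRα−Sca-1−, and 66.7 and 83.8 for PDGFRα+Sca-1− cells. Neither yardstick tests the counts. The simulated scatter holds no difference between arrays or animals, and a shared array by itself raises the overlap above that of independent lists. Cd34, Mfap5, Cd248, Mndal, Efhd1 and Ebf2 marked PDGFRα+Sca-1+ cells. Dmp1, Krtap17-1, Pla2g10, Hpgd, Cdh2 and Entpd3 marked PDGFRα+Sca-1− cells; Entpd3 was 10.1-fold above PDGFRα−Sca-1− cells. Sfrp5, Fgg, Scube2, Pbk, Notum and Cdca5 marked PDGFRα−Sca-1− cells, and of these Pbk, a mitotic kinase, and Cdca5, a cohesion factor, were 9.01-fold and 8.42-fold above PDGFRα+Sca-1− cells. Notum, a secreted Wnt inhibitor, was 8.45-fold above PDGFRα+Sca-1− cells and at least 20.4-fold above PDGFRα+Sca-1+ cells.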

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

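The following values come from probe sets that entered no comparison of genes, and both were singled out only after they were seen; no explanation of either was tested. Poly-A spike-ins, bacterial transcripts added before labelling, were brighter on the PDGFRα+Sca-1− than on the PDGFRα−Sca-1− array for 8 of 8 probe sets, with a median ratio of 1.91 and a range of 1.67 to 2.49. Their median ratio was 0.445 for PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells, while 18 probe sets for spike-ins added at hybridisation gave 1.04 and 0.838 for the same comparisons. Among 10092 probe sets without a single gene name, 4146 were above the floor on at least 1 array, 308 were at least 2-fold higher in PDGFRα+Sca-1+ cells than in both other populations, and 308 were at least 2-fold lower.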

How the results depend on the processing

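All alternatives were planned, and none was added after the data were seen. No paired analysis was possible because each population had 1 array. The 12 counts of genes were recomputed 108 times in all, and 88 of the values lay within 1.5 times the main count. The exceptions came from the threshold and the floor. At 3-fold, 841 genes were higher and 693 lower in PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells, 202 and 190 in PDGFRα+Sca-1− over PDGFRα−Sca-1− cells, and 846 and 714 in PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells. Apart from both other populations at 3-fold were 631 genes higher and 417 lower in PDGFRα+Sca-1+ cells, 125 and 51 in PDGFRα−Sca-1− cells, and 121 and 26 in PDGFRα+Sca-1− cells. A stricter size rule lowers every count by construction. With the floor at the 67th percentile, which compares fewer genes, PDGFRα+Sca-1− over PDGFRα−Sca-1− cells gave 365 higher and 388 lower. The genes apart from both others were then 238 higher and 111 lower in PDGFRα−Sca-1− cells and 86 lower in PDGFRα+Sca-1− cells. With the floor at the 33rd percentile, which compares more genes, 294 were lower in PDGFRα−Sca-1− cells and 255 in PDGFRα+Sca-1− cells than in both others, and with the pseudocount 88 were lower in PDGFRα+Sca-1− cells. Of 743 recomputed list medians over 93 medians, 714 moved by less than the scatter between probe sets, 28 moved by more and 1 reversed, where a reversal was counted only for a main log2 ratio of at least 1 either way. With the mean over probe sets the fibroblast median was 3.13 and the osteocyte median −0.30 in PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells. With the floor at the 67th percentile the cell cycle median in PDGFRα+Sca-1− over PDGFRα−Sca-1− cells rose from −1.46 to just above −1 and the erythroid median −0.49 in PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells. The endothelial list in PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells had a median of −0.31 with the floor at the 33rd percentile, against 1.42 in the main setting, and the cause was not tested. Of 10822 recomputed single-gene ratios, 9954 moved by less than that scatter, 866 moved by more and 2 reversed. With the mean over probe sets the log2 ratio of Tgfbr2 in PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells was −0.48 and that of Phex in PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells −0.90, since their probe sets lay on opposite sides. No count, list median or single gene reversed or moved past these limits under the values as deposited, median centring or quantile normalization. These settings could hardly move them, since the arrays already shared a trimmed mean when deposited. Median centring shifted the median log2 ratio of all genes in PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells only from 0.065 to 0.007. Their stability therefore says little, and the totals above include these settings. Genes near the floor of 93.2 are limited by signal over background and have bounds only.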

Other observations

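The tests of explanations in this part were chosen only after the result was seen, except that under the 3 other scalings, which was planned. Glycolysis genes were at least 2-fold lower in PDGFRα+Sca-1+ than in PDGFRα−Sca-1− cells for 8 of 15 members and higher for 0, with a median log2 ratio of −1.08. The phosphofructokinase Pfkl was 5.53-fold, Aldoc at least 4.53-fold, the glucose transporter Slc2a1 4.47-fold and the hexokinase Hk1 3.10-fold lower, with 2 of 3 Pfkl probe sets on that side. Against PDGFRα+Sca-1− cells 5 of the 15 were lower and 0 higher, with a median of −0.51 at percentile 0.93 of the random lists. Between the Sca-1− populations 14 of 15 were within 2-fold. The median there was still −0.40 at percentile 0.36, lower in PDGFRα+Sca-1− cells, so both steps were of like size. All 24 oxidative phosphorylation genes and all 17 ribosomal protein genes compared were within 2-fold in each of the 3 comparisons. Immediate early and dissociation stress genes were within 2-fold for 23, 24 and 25 of 26 members in PDGFRα+Sca-1+ over PDGFRα+Sca-1−, PDGFRα+Sca-1− over PDGFRα−Sca-1− and PDGFRα+Sca-1+ over PDGFRα−Sca-1− cells. Egr3 was 3.93-fold and Btg2 3.76-fold lower in PDGFRα+Sca-1+ than in PDGFRα+Sca-1− cells. Of 12 Hox genes compared between the PDGFRα+ populations, Hoxd9 (3.86-fold) and Hoxd8 (2.57-fold) were higher in PDGFRα+Sca-1+ cells, Hoxc8 (3.15-fold) and Hoxa3 (at least 2.63-fold) lower and 8 within 2-fold. Of 8 Notch pathway genes, Notch3 (3.20-fold) and Jag1 (2.18-fold) were higher and 6 within 2-fold.

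The remaining values of cell type markers are given for PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells. Smooth muscle and pericyte genes were higher for 3 of 10 members, among them Rgs5 (8.92-fold) and Abcc9 (4.96-fold), and lower for 2, among them Cspg4 (4.90-fold). Of 7 endothelial genes compared, 3 were higher, among them Ramp2 (17.6-fold) and Tek (at least 9.53-fold), and Pecam1 was under the floor on all 3 arrays. Adipocyte genes were higher for 3 of 6 members, among them Lpl (7.92-fold), and lower for 1. Schwann cell genes were lower for 4 of 8 and higher for 0, with S100b 5.31-fold and Cdh19 at least 7.48-fold lower. Of 4 skeletal muscle genes compared, Tnni2 (at least 23.2-fold) and Acta1 (at least 6.84-fold) were lower. Osteoclast genes were higher for 2 of 5, among them Itgb3 (7.68-fold), and lower for 1. Of 5 monocyte and macrophage genes, Cd14 was 5.33-fold lower and Lyz2 2.32-fold higher. Of 5 megakaryocyte and platelet genes, Itga2b was 3.44-fold higher and 4 were within 2-fold. Most immune lists were largely under the floor: 3 of 15 B lineage genes with a value had a ratio, with Ebf1, also held by the reticular stroma list, 18.9-fold higher, and 4 of 9 plasma cell genes did, all within 2-fold. The only T and NK cell gene compared was Thy1, which is also in the progenitor surface list, and the only mast cell and basophil gene compared was Gata2, 2.46-fold lower.

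Cell cycle genes were higher in PDGFRα−Sca-1− than in PDGFRα+Sca-1− cells, and their median lay at percentile 0 of the random lists matched on signal, which argues against 1 scaling error that moves all genes of like signal alike; the 3 other scalings, with a highest median log2 PDGFRα+Sca-1− over PDGFRα−Sca-1− ratio of −1.46, shifted the median of all genes too little to decide. A candidate explanation is erythroid cells that passed the Ter119 gate, but for haemoglobin-making cells the values speak against it in this comparison, though on few probe sets. Of 15 globin probe sets on the array, only 4 were above the floor in either population, 3 of them shared between globin genes. These 4 had a median log2 PDGFRα+Sca-1− over PDGFRα−Sca-1− ratio of 0.15 with 1 bound entered at the floor. The 3 shared ones, above the floor on both arrays with signals up to 1050 and 945, had −0.04 with an SD of 0.25. Against PDGFRα+Sca-1+ cells, where the cell cycle median was −1.69, the globin median was −2.26. The 3 shared probe sets had log2 ratios from −2.85 to −2.16, with signals there of at most 213. The other, under the floor in PDGFRα−Sca-1− cells, was higher by a log2 ratio of at least 1.02. Median globin signals were 768 in PDGFRα−Sca-1−, 831 in PDGFRα+Sca-1− and 167 in PDGFRα+Sca-1+ cells. By themselves the 3 shared probe sets go with haemoglobin-making cells in this comparison. Yet globin signals were alike on the Sca-1− arrays, while the cell cycle median between those arrays was −1.46. The cell cycle median of PDGFRα+Sca-1+ over PDGFRα+Sca-1− cells was −0.22, with 14 of 19 genes within 2-fold. A further 8 genes were under the floor on both of these arrays, and values entered at the floor draw ratios toward equality. These values, from 1 array each, argue against haemoglobin-making cells as the whole of the −1.69, and a part stays open. Earlier erythroid precursors cannot be told apart from other dividing cells, endosteal or cartilage, in the comparison with PDGFRα+Sca-1− cells. The erythroid list had a median of −0.84 there, with only 3 of 14 members over 10 times the floor. Tfrc, its brightest, is used by dividing cells in general. A larger dividing fraction in the PDGFRα−Sca-1− population remains an untested biological explanation.

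Of the neutrophil and granulocyte precursor list, 11 genes were above the floor on both PDGFRα+ arrays, with signals of at most 712. A candidate explanation is a common source of myeloid RNA, which would keep the genes at 1 ratio between these arrays. Over the 11 genes the SD of that log2 ratio was 0.91, against 0.60 between probe sets of a gene, with Lcn2 at 2.38 and Camp at 0.79. If the genes are taken as independent, the lower 95% bound of this SD was 0.63. Over the 7 at least 2-fold higher in PDGFRα+Sca-1− than in PDGFRα−Sca-1− cells the SD was 0.23. These were chosen by their level on an array of the ratio itself, which narrows the SD, so that value decides nothing. A common source and expression by the sorted cells cannot be told apart, because 0 of the 11 genes lay over 10 times the floor, and nor can CD45+ cells that passed the gate be told apart from free RNA, because Ptprc had a signal of at most 74.1, under the floor.

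Chondrocyte genes were not lowered evenly in PDGFRα+Sca-1+ cells: the signal left, relative to the mean of the Sca-1− populations, ran from 1.02% for Col9a2 to 138% for Cilp, with 86.7% for Comp. Sca-1− cells carried over in a common share would leave a common percentage only if PDGFRα+Sca-1+ cells made none of these genes themselves. Over 22 genes the SD of the log2 value was 2.08 with a lower 95% bound of 1.60, against 0.60 between probe sets of a gene. This spread argues only against carry-over as the sole source of all 22, and a small share behind the lowest members stays open. The bounds given here treat the genes as independent, which genes of 1 list may not be, so they only describe the spread. Some members, such as Matn1 and Col10a1, also differed between the Sca-1− arrays, so the mean is not the signal of 1 source. Saturation of bright probe sets could make shares unequal, but among 10 genes with a mean Sca-1− signal under 15000 the SD was 2.32 with a lower bound of 1.60; Comp and Prg4 lie above that limit, so their own shares stay open to it. Carry-over of about 1% of the Col9a2 signal stays open, since no value forbids a share of that size. No biological explanation was tested.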
